A study of Drosophila melanogaster with 33 samples.

How the data were processed

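The series holds 33 two-colour arrays of midgut RNA from Canton S Drosophila melanogaster, with 3 arrays for each of 11 stages from 18 h before to 12 h after puparium formation. Per the labels, the RNA was amplified by in vitro transcription, the stage sample carried Cy5 and a pooled reference Cy3, and the replicate hybridizations used independent samples. The reference was a mixture of 10 of the stages, all but 10 h. The deposited values are log2 ratios of stage sample to reference, 1 value per probe and array. Neither the base of the logarithm, nor the direction, nor any centring is stated by the authors, and background correction and normalization are not given in the sources used here.

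Base and direction were inferred from the reference mixture. If ratios are stage over reference, 2 raised to the values, averaged over the 10 pooled stages, should be near 1 constant for every probe. The SD over 7257 probes of the log2 of that mean was 0.117, against 0.509 with the sign reversed. With natural logarithms the SDs were 0.204 and 0.792. Equal mixing of 10 stages limits a ratio to 10, or 3.32 on the log2 scale. Of 121255 stage means of the pooled stages 1 lay above that limit in base 2, 149 with natural and 1865 with decimal logarithms.

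The value table had 20000 entries, of which 14064 held at least 1 value and 5936 none. Array medians ran from -0.029 to 0.118. Their span of 0.148 was below the limit of 0.2 fixed for re-centring, so values were used as deposited. Arrays with the replicate letter a held fewer values (mean 8948.6) than those with b (11998.5) or c (12486.2), and 2645 probes had no value on any a array. No 2 arrays were duplicates. Intensities were not used here, and the number of arrays limits the precision.

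Probes were joined to gene symbols through the annotation table of the platform and a RefSeq gene table (Release 6 plus ISO1 MT) used for names only. In this way 10828 probes had 1 gene (9904 different genes, 793 of them with more than 1 probe), 227 had several, 3009 were not in the annotation table, and 4 had the platform symbol only. Values of named genes are means over the probes of the gene. The list members Npc2, Ald, lat, Dpt and Dl could not be resolved.

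Stages were compared with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, in 1 linear model over all 33 arrays with moderated variances. Probes needed at least 2 values in each stage compared, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were the moderated F test over all stages, the 10 steps between neighbouring stages, and 4 longer changes: late larval (18 h BPF to 0 h), early prepupal (0 h to 6 h), late prepupal (6 h to 12 h) and whole interval (18 h BPF to 12 h). Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9. Simulated data had the variances and missing values of the 7257 probes measured in every stage, with independent normal noise. Changes of 0.5, 1 and 2 on the log2 scale were added at 12 h to 67, 67 and 66 probes. In the whole interval comparison 4.5%, 61.2% and 93.9% of them were recovered, and 3 calls, or 2.8%, were false. In the data 2220 of 12704 probes were called in that comparison, a larger share than was changed here. The recovered shares are therefore not those of the real comparison.

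Gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. The 26 lists covered ecdysone regulators, other ecdysone-induced genes, cell death, autophagy, lysosomal hydrolases, digestive serine proteases, digestive carbohydrases with lipases and lysozymes, peritrophic matrix, V-ATPase, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, proteasome, DNA replication and cell cycle, P450 and GST, antimicrobial and peptidoglycan recognition, small heat shock proteins, matrix and adhesion, EGFR, Notch and other signals, and markers of progenitors, enteroendocrine cells, visceral muscle, fat body, salivary gland, haemocytes and Malpighian tubule. Lists were tested with camera at a preset correlation of 0.01 on the 1993 named genes with values on all arrays, which left 13 lists with at least 5 genes. Genes were named by these rules: the 6 largest rises and 6 largest falls of each longer change among named probes past the threshold whose arrays of 1 stage all lay on one side of those of the other, up to 3 called members per list and direction, the member of each marker list with the largest change, the 2 largest rises and 2 largest falls of named probes past the threshold per step, and the 2 genes per stage with the largest excess, ranked by probe. The genes per stage were ranked among named probes past the moderated F test. Of 16 regulators and cell death genes always to be named, 10 were found by name among the annotated probes.

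The alternatives were arrays centred on their medians, quantile normalization, no filter on missing values, only probes with values on all arrays, spots of a gene averaged, the replicate letter as a block, array weights, robust variances with a trend, a change of at least 2-fold, the numbers in the array titles as covariates (their meaning is not stated), only the 6 arrays compared, leaving out each array, and for lists an estimated correlation and the fry test. A fit of replicates b and c alone was added after seeing the data.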

Results

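The data follow the midgut of Canton S Drosophila melanogaster through metamorphosis, when the larval gut epithelium is broken down and an adult one is built. Midguts from 11 stages were profiled: 18 h and 4 h before puparium formation (BPF), puparium formation itself (0 h), and 2, 3, 4, 5, 6, 8, 10 and 12 h after it (APF). Each stage has 3 arrays, which the labels describe as independent samples, and each of the 33 arrays compared amplified midgut RNA of its stage (Cy5) with a pooled midgut reference (Cy3). Values below are log2 ratios of stage over reference, so a difference between stages of 1 is a doubling. Base and direction were inferred from the values and from the make-up of the reference. Of the 14064 probes with any value, single arrays held between 7006 and 13966, and 2249 probes had a value on every array. Signal and background intensities were not used here, so the number of arrays sets the precision. Arrays of the same stage correlated across probes at 0.59 to 0.86, with a median of 0.75. Arrays of different stages ranged from -0.53 to 0.85, and 100 of the 528 pairs lay below -0.3.

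Single genes were ranked at each stage by their excess over their own mean at the other stages. At 18 h BPF the leading genes CG6839 and CG3819 stood at 3.39 ± 0.35 and 3.15 ± 0.40 (SD, n = 3), which were excesses of 7.40 and 6.92. At 4 h BPF the leading genes were CG6271 and CG33307, with excesses of 5.63 and 5.31, and at 0 h they were CG15818 and CG12951, with 4.76 and 4.72. The excesses were smaller in the following hours. Ir21a, an ionotropic receptor gene, led or came next at 2, 3 and 4 h APF (2.40, 2.43 and 1.88), beside CG11865 at 2 h (2.68), CG8329 at 3 h (2.61) and CG14567 at 4 h (1.75). Fer3 (2.26) and CG11786 (2.14) followed at 5 h, and Osi14 (3.13) and CG11786 (2.94) at 6 h. From 8 h on the excesses were again larger. At 8 h CG6484 (5.39) and Irk2, an inward rectifier potassium channel (3.19), led. CG7997 (5.52) and Treh, the trehalase gene (4.37), led at 10 h, and CG11570 (7.38) and CG7997 (6.81) at 12 h. The ranking is by single probe, and on the gene means given here Cht8 had a larger excess at 10 h than Treh. A large excess did not make a stage the highest of a gene. CG33307 was highest at 18 h BPF, CG15818 at 4 h BPF, CG11865 at 0 h and Ir21a at 3 h APF. Fer3, CG11786 and Osi14 were highest at 8 h, Irk2 at 10 h and CG7997 at 12 h. The leading genes were picked among probes past the moderated F test. Their adjusted p-values in it, from 2.55e-15 to 4.78e-06, are therefore no separate evidence.

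In total 4145 of the 7257 probes with at least 2 values in every stage passed that test (57.1%). Among them 3296 differed at least 2-fold and 1302 at least 4-fold between their highest and lowest stage, and the median fold was 2.77. The highest stage was most often 2 h APF (574 probes, 13.8%), followed by 18 h BPF (512 probes, 12.4%). The peak at 2 h was not particular to these probes. Among tested probes that did not pass, 2 h was also the most frequent highest stage (534 probes). The 2 h arrays had medians of 0.118, 0.056 and 0.087, and values were not centred. The lowest was most often 18 h BPF (835 probes, 20.1%) or 12 h APF (762 probes, 18.4%).

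**Figure D1:**
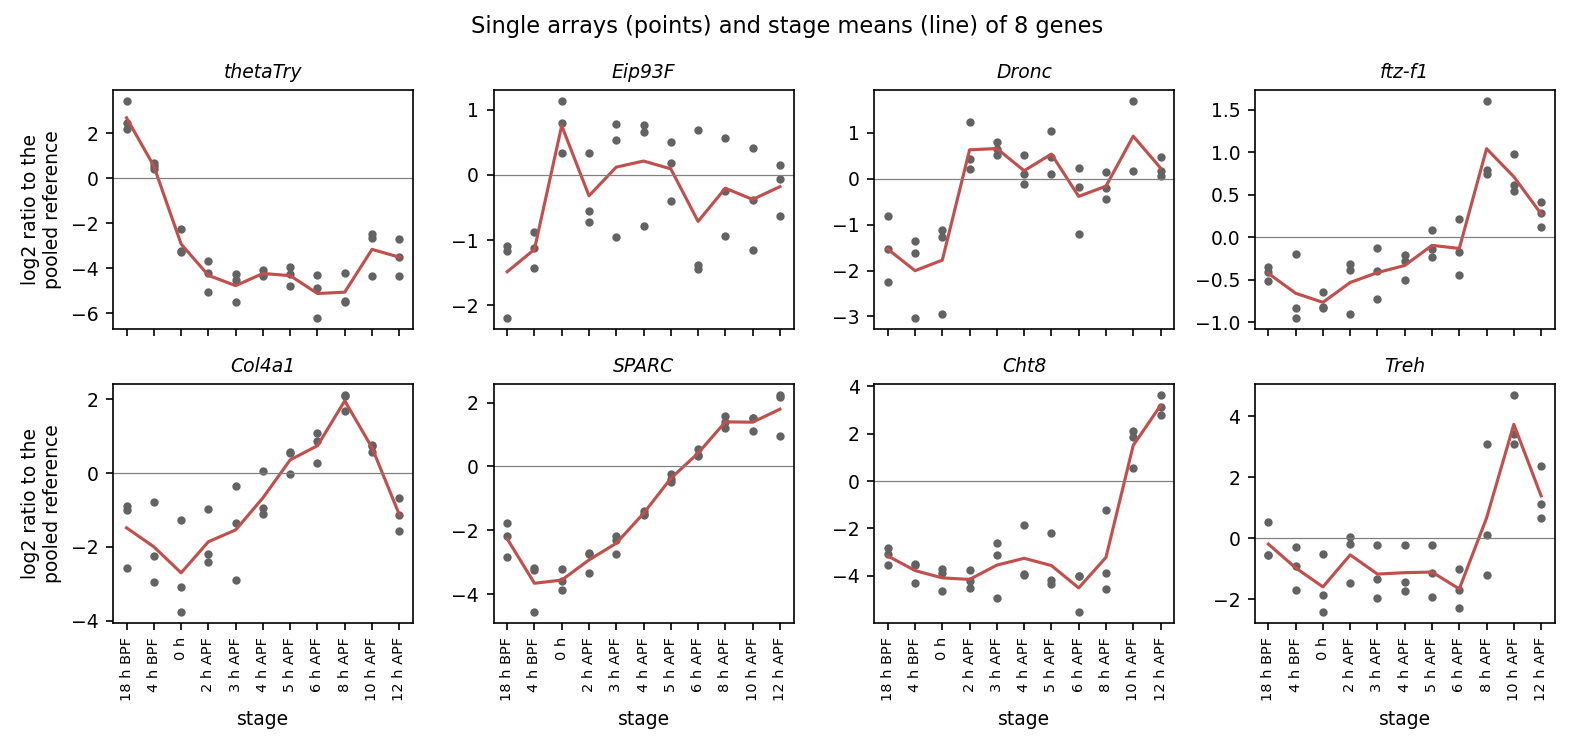
Log2 ratio to the pooled reference (y axis) at the 11 stages (x axis) for 8 named genes, with each array as a point and the stage means joined by a line. thetaTry starts at 2.68 and lies at -5.13 at 6 h APF, while Cht8 lies at -4.52 at 6 h and at 3.19 at 12 h.

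The regulators of the ecdysone response and the cell death genes fixed for naming followed different courses. ftz-f1, a nuclear receptor of the mid-prepupal response, lay at -0.76 ± 0.11 (SD, n = 3) at 0 h and was highest at 8 h APF, at 1.05 ± 0.48 (n = 3), with an adjusted p of 2.7e-07 over the time course. Hr3 peaked at 2 h (0.42 ± 0.57, n = 2) and was lowest at 12 h (-1.57 ± 1.11, n = 2; adjusted p = 0.00143). Hr39 was likewise highest at 2 h (0.68 ± 0.35) and lowest at 6 h (-0.81 ± 0.75; adjusted p = 0.000566). Eip93F, a regulator of steroid-triggered cell death, climbed from -1.49 ± 0.62 at 18 h BPF to 0.76 ± 0.40 at 0 h (adjusted p = 0.0214 over the time course). EcR, the ecdysone receptor, was highest at 4 h BPF, at 1.15 ± 0.96 (n = 2), and lowest at 6 h (adjusted p = 0.00585). br did not pass the test (adjusted p = 0.321). Dronc, the initiator caspase, lay between -2.01 and -1.53 up to 0 h and at 0.63 ± 0.55 at 2 h. Its highest stage mean was at 10 h, from replicates a and c alone (adjusted p = 5.09e-06 over the time course). Diap2, a caspase inhibitor, did not pass (adjusted p = 0.178).

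Dark, the apoptosome adaptor, and Blimp-1 had fewer than 2 values at some stages and so had no test over the whole course. The means of Dark were highest at 4 h BPF (1.43 ± 0.23) and lowest at 8 h APF, at -1.21, while those of Blimp-1 lay between -0.26 and 0.37. Eip74EF, Eip75B, Hr4, rpr, hid and Diap1, which were to be named as well, were not analysed here.

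Between neighbouring stages probes passed the test up to 2 h APF and again from 6 h on, and none passed in the hourly steps between. From 18 h to 4 h BPF 751 probes differed (409 higher, 342 lower). Ranked by single probes, the rises were led by CG12951 (4.07 ± 0.45, SE) and Agpat2 (3.56 ± 0.27), an enzyme of phospholipid synthesis. The falls were led by CG6839 (-3.43 ± 0.49) and CG14205 (-2.37 ± 0.54) in the same ranking. On the gene means given here, CG3819 fell by more than CG14205. From 4 h BPF to 0 h 315 differed (163 higher, 152 lower, against 143 and 163 with centred arrays and 141 and 188 under quantile normalization), with CG8249 (3.40 ± 0.23) and CG8329 (2.98 ± 0.70) rising most and CG3819 (-3.79 ± 0.41) and CG17826 (-3.55 ± 0.55) falling most. From 0 h to 2 h APF 608 differed (351 higher, 257 lower). Galphaf (3.18 ± 0.30) and CG16758 (3.07 ± 0.42) rose and CG8745 (-3.59 ± 0.55) and CG6277 (-3.57 ± 0.64) fell. Changes of at least 2-fold were mostly falls in the first 2 of these steps (222 higher and 261 lower, then 107 and 139) and mostly rises in the third (227 and 202). Under quantile normalization this last step had 254 probes higher and 321 lower (44.2% higher, against 57.7%). The call of CG14205 was lost without 18 h BPF replicate b, where its change was -1.72, and that of CG8329 without any one of 4 h BPF replicates a and b and 0 h replicates a and b (2.68, 2.76, 3.04 and 2.93). Single arrays moved these counts by more than 1.5 times: without 4 h BPF replicate b the first step had 461 probes, without 4 h BPF replicate b, 0 h replicate b or 0 h replicate c the second had 175, 158 and 206, and without 0 h replicate a the third had 298.

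No probe passed limma's moderated test from 2 to 3, 3 to 4, 4 to 5 or 5 to 6 h APF. Unadjusted p-values under 0.05 were found for 259, 329, 369 and 749 probes in these steps, out of 11210, 11443, 11670 and 8922 tested. These were 2.3%, 2.9%, 3.2% and 8.4%, and the first 3 shares lay below what chance alone would give at that threshold. Without single arrays the counts for the last 3 of these steps reached 1 (without 4 h replicate c), 1 (without 5 h replicate c) and 8 (without 6 h replicate b or c). Over the 4 h from 2 h to 6 h together, 1100 of 8950 probes differed, 444 higher and 656 lower at 6 h.

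From 6 to 8 h 300 probes differed (199 higher, 101 lower), among them Cpr51A, a cuticular protein gene (4.56 ± 0.59, SE, with 2 arrays per stage), Irk2 (4.08 ± 0.54) and, in the other direction, Cyp313a4 (-2.85 ± 0.54) and Srg2 (-2.67 ± 0.72). From 8 to 10 h 173 differed (91 higher, 82 lower), with Cht8, a chitinase-like gene (4.74 ± 0.69), and CG7997 (4.72 ± 0.60) the named genes with the largest rises. The largest falls of named probes were those of CG12164 and CG3108 (-2.58 ± 0.52). For CG12164 1 probe passed, at -2.82, and the mean over its probes, at -2.56 ± 0.71, did not (adjusted p = 0.0607). From 10 to 12 h 132 probes were higher and 180 lower. CG11570 (4.14 ± 0.46) and Cyp12a4 (4.13 ± 0.40) rose, and CG1213 (-4.79 ± 0.38) and CG6484 (-4.74 ± 0.48) fell. The call of Srg2 was lost under quantile normalization (-2.47) and without 6 h replicate c or 8 h replicate a or b (-1.66, -2.49 and -2.30), and that of CG3108 without 8 h replicate a or c or 10 h replicate a (-2.24, -2.44 and -2.13). The 6 to 8 h count was 120 without 6 h replicate a, 185 without 6 h replicate c, 147 without 8 h replicate a and 105 without 8 h replicate b. The 8 to 10 h count was 73 without 8 h replicate a, 59 without 8 h replicate c, 80, 98 and 292 without 10 h replicates a, b and c, and the 10 to 12 h count was 194 without 12 h replicate a.

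**Figure D2:**
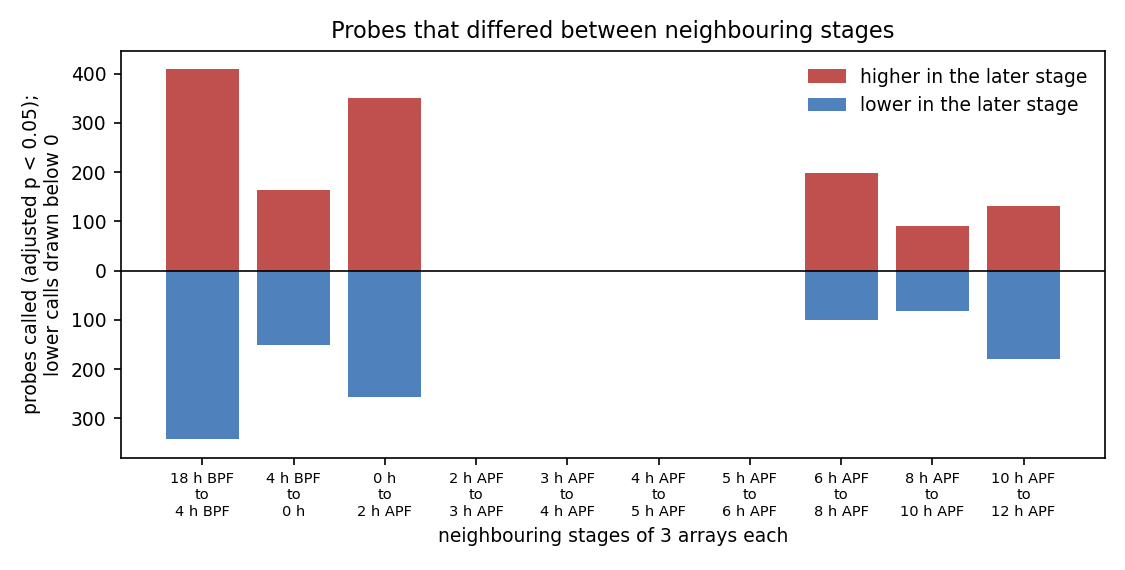
Probes past an adjusted p of 0.05 (y axis, number of probes) between neighbouring stages of 3 arrays each (x axis), with probes higher in the later stage drawn above 0 and probes lower in it below 0. The 4 steps between 2 h and 6 h APF have 0 probes, and the step from 18 h to 4 h BPF has 751.

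Digestive genes fell and proteasome genes rose between 18 h BPF and 0 h, the end of larval life. Of 27 serine proteases of the trypsin and Jonah families 23 fell, among them thetaTry, from 2.68 ± 0.65 to -2.93 ± 0.58 (SD, n = 3; change -5.61 ± 0.50, SE; adjusted p = 2.96e-09). None rose, and the median change was -3.25. Of 18 carbohydrases, lipases and lysozymes 11 fell, such as mag, a lipase (-5.34 ± 0.62), and LysS, a lysozyme (-4.73 ± 0.42), and 1 rose. Subunits of the proteasome, which degrades ubiquitinated proteins, rose in 22 of 29 cases, Rpn2 by 1.73 ± 0.28 and Rpn5 by 1.58 ± 0.24, with none lower. Autophagy genes also moved upward where they moved: 7 of 21 rose, including Atg7 (2.06 ± 0.22), Atg18b (1.74 ± 0.37) and Atg2 (1.31 ± 0.22), and none fell.

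The V-ATPase, the proton pump that acidifies gut lumen and vesicles, had 10 of 20 subunit genes lower and none higher, with Vha100-4 at -2.55 ± 0.33, Vha100-5 at -1.80 ± 0.27 and VhaPPA1-1 at -1.13 ± 0.21. Of 11 glycolytic genes 5 fell, among them Gpdh1 (-1.84 ± 0.35), Gapdh1 (-1.49 ± 0.19) and Pgi (-1.25 ± 0.22), and 1 rose. The peritrophic matrix, the lining that separates food from epithelium, had 2 of 6 genes lower, Muc55B (-3.11 ± 0.61) and Peritrophin-15a (-2.20 ± 0.59). Cytosolic ribosomal protein genes did not pass in any of 33 cases, and oxidative phosphorylation genes in 1 of 52, which was lower. DNA replication and cell cycle genes rose in 5 of 17 cases, with PCNA, the replication clamp, up by 1.37 ± 0.28. Among cell death genes Buffy, of the Bcl-2 family, rose by 1.98 ± 0.26 and the caspase gene Damm fell to a change of -2.07 ± 0.23, with 2 of 11 higher and 1 lower in all. Of 12 ecdysone regulators 3 rose: Eip93F (2.24 ± 0.52), Hr78 (0.71 ± 0.18) and Hr39 (0.88 ± 0.29), the last of which was lost without any one of 18 h BPF replicates a and b and 0 h replicates b and c (changes 0.84, 0.86, 0.69 and 0.86). EcR, br, ftz-f1, Hr3, Dronc and Diap2 did not pass, at -0.30, 0.53, -0.34, 0.90, -0.24 and -0.13. Visceral muscle markers were lower in 4 of 10 cases, such as Mlc2 (-2.47 ± 0.30) and Mlc1 (-1.06 ± 0.25), and none was higher.

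The genes with the largest rises were CG11865 (4.42 ± 0.52, SE), Agpat2 (4.33 ± 0.27), CG12951 (4.21 ± 0.45), the glutathione transferase gene GstE3 (3.96 ± 0.30), CG5171 (3.47 ± 0.38) and CG2201 (3.35 ± 0.20). The largest falls were those of CG6839 (-6.86 ± 0.49), CG3819 (-6.32 ± 0.41), CG17633 (-5.88 ± 0.93), thetaTry, CG4367 (-5.49 ± 0.81) and mag. The genes were picked among probes whose arrays of one stage all lay on one side of those of the other. They had also passed limma's test. Their adjusted p-values in it, from 4.24e-12 to 2.09e-05, are therefore no separate evidence. In total 1777 of 10204 probes differed, 1028 higher and 749 lower at 0 h, in 1390 named genes, and 560 higher and 558 lower by at least 2-fold. Adjusted over the list alone, 24 serine proteases, 13 other digestive enzymes, 12 V-ATPase subunits and 5 glycolytic genes fell, and 26 proteasome and 8 autophagy genes rose. The competitive camera test gave adjusted p-values of 1.84e-08 for serine proteases, 1.27e-05 for other digestive enzymes and 9.72e-05 for the proteasome. By the same test they were 0.00211 for the V-ATPase, 0.00213 for glycolysis and 0.0896 for autophagy. Autophagy had only 5 genes measured on every array. Without the filter on missing values its 23 genes were higher as a list (adjusted p = 0.000223 by camera at the preset correlation). The correlation was estimated only for the 5 genes, which then had adjusted p = 0.213 by camera. With an estimated correlation between genes the other digestive enzymes kept their call (adjusted p = 0.0178 with an estimated correlation). The call was lost for serine proteases (adjusted p = 0.102 with an estimated correlation), the proteasome (adjusted p = 0.149 with an estimated correlation), the V-ATPase (adjusted p = 0.213 with an estimated correlation) and glycolysis (adjusted p = 0.119 with an estimated correlation). Trypsin, Jonah, lysozyme and amylase genes have near-identical copies, so values of single members are uncertain because probes may bind more than 1 of them.

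In the first 6 h after puparium formation, genes of oxidative phosphorylation and glycolysis rose in most tested cases, and serine proteases fell further. Of 26 serine proteases 25 fell and none rose, with Jon65Aiv going from 0.78 ± 0.58 at 0 h to -4.02 ± 0.60 at 6 h (SD, n = 3; change -4.80 ± 0.45, SE; adjusted p = 2.5e-09) and alphaTry changing by -4.51 ± 0.48. Proteasome genes, higher at 0 h than before, now fell in 24 of 28 cases, Rpn2 to a change of -1.98 ± 0.28 and Rpn3 to -1.81 ± 0.25. Oxidative phosphorylation genes rose in 25 of 46 cases, with the cytochrome oxidase subunits COX5B at 1.25 ± 0.25 and COX4 at 1.21 ± 0.22, and none fell. Of 10 glycolytic genes 7 rose, led by Pglym78 (2.47 ± 0.25), Pfk (2.09 ± 0.21) and Gapdh1 (1.74 ± 0.19).

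Among matrix and adhesion genes 4 of 9 rose: SPARC, a collagen-binding protein (3.97 ± 0.31), the type IV collagen gene Col4a1 (3.45 ± 0.58), the perlecan gene trol (1.57 ± 0.29) and Timp, a metalloproteinase inhibitor (1.38 ± 0.26). The other direction held 2, the integrin genes scb (-0.99 ± 0.26) and mys (-1.60 ± 0.59), of which mys was lost without 0 h replicate b or c or 6 h replicate a (-1.18, -1.33 and -0.24). Of 5 haemocyte markers 1 rose, the same Col4a1, and 3 rose when adjusted over the list alone, with a median change of 0.54. Without the filter on missing values 9 haemocyte markers could be tested as a list by camera and were higher (adjusted p = 0.0118 at the preset correlation). The haemocyte list shares Col4a1 and vkg with the matrix list, so its call is not separate from that of the matrix genes. NimC1 and Pxn had 1 array at 0 h. V-ATPase genes rose in 10 of 20 cases, with Vha13 at 1.46 ± 0.34. Autophagy genes fell in 6 of 19 cases, such as ref(2)P (-1.86 ± 0.22) and Atg7 (-1.69 ± 0.24). Peritrophic matrix genes fell in 3 of 6, Peritrophin-15b (-4.37 ± 0.41), Peritrophin-15a (-3.98 ± 0.59) and Muc55B (-2.95 ± 0.61). Other digestive enzymes were split, 3 of 17 higher and 4 lower. The alpha-glucosidase gene tobi rose by 4.68 ± 0.32 and the maltase gene Mal-A2 by 2.83 ± 0.38. Cyp18a1, which inactivates ecdysone, rose by 3.38 ± 0.41.

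Of the ecdysone regulators 1 of 10 rose and 2 fell. ftz-f1 changed by 0.63 ± 0.23 (adjusted p = 0.0361), a call lost without 0 h replicate a or b or 6 h replicate b or c (0.60, 0.60, 0.46 and 0.65) and under quantile normalization (0.64). Hr39 changed by -1.18 ± 0.29 (adjusted p = 0.0022). Eip93F changed by -1.47 ± 0.52 (adjusted p = 0.0356), lost without 0 h replicate a or b or 6 h replicate a or c (-1.45, -1.28, -1.13 and -1.11) and under quantile normalization (-0.97). br narrowly missed the threshold, at -0.76 ± 0.29 (adjusted p = 0.0539), and EcR, Hr3 and Diap2 did not pass, at -0.17, -0.14 and 0.25. Among 11 cell death genes Dark fell to a change of -1.51 ± 0.20 (adjusted p = 1.37e-05) and Dronc rose by 1.39 ± 0.47 (adjusted p = 0.0263), which was lost without 0 h replicate a or 6 h replicate b or c (0.81, 1.29 and 1.08). The third cell death call was the caspase gene Strica, at -1.02 ± 0.37, lost without 0 h replicate b or c or 6 h replicate a or c (-1.04, -0.81, -0.93 and -0.91).

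The largest rises were those of CG15096 (5.41 ± 0.47, SE), the phagocytic receptor gene NimC4 (5.26 ± 0.51), CG1213 (5.13 ± 0.38), Fer3 (5.03 ± 0.45), CG15169 (4.85 ± 0.44) and the serpin gene Spn28Dc (4.76 ± 0.45). CG15818 (-6.89 ± 0.68), CG12951 (-6.75 ± 0.45), CG10912 (-6.23 ± 0.54), CG15044 (-6.07 ± 0.37), CG11912 (-6.01 ± 0.60) and Jon65Aiii (-6.01 ± 0.96) fell most. In total 1983 of 8038 probes differed, 1068 higher and 915 lower at 6 h, in 1605 named genes. Among changes of at least 2-fold the balance turned, with 582 higher and 634 lower. Adjusted over the list alone, 25 serine proteases, 26 proteasome and 7 autophagy genes fell, while 28 oxidative phosphorylation, 8 glycolytic, 13 V-ATPase and 5 matrix genes rose and 2 matrix genes fell. By camera the adjusted p was 5.54e-08 for serine proteases, 1.65e-05 for the proteasome, 0.000185 for oxidative phosphorylation, 0.000545 for glycolysis, 0.0199 for the V-ATPase and 0.0211 for the matrix list. All of these calls were lost with an estimated correlation. Serine proteases, proteasome and glycolysis then each had adjusted p = 0.122 with an estimated correlation, the matrix list adjusted p = 0.145 with an estimated correlation, oxidative phosphorylation adjusted p = 0.309 with an estimated correlation and the V-ATPase adjusted p = 0.321 with an estimated correlation. The V-ATPase call was also lost without 0 h replicate a (adjusted p = 0.0518) or 6 h replicate b (adjusted p = 0.0547), in a range from 0.00113 to 0.321 over the alternatives that use camera, and the matrix call without 6 h replicate b (adjusted p = 0.0501), in such a range from 0.00668 to 0.145.

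**Figure D3:**
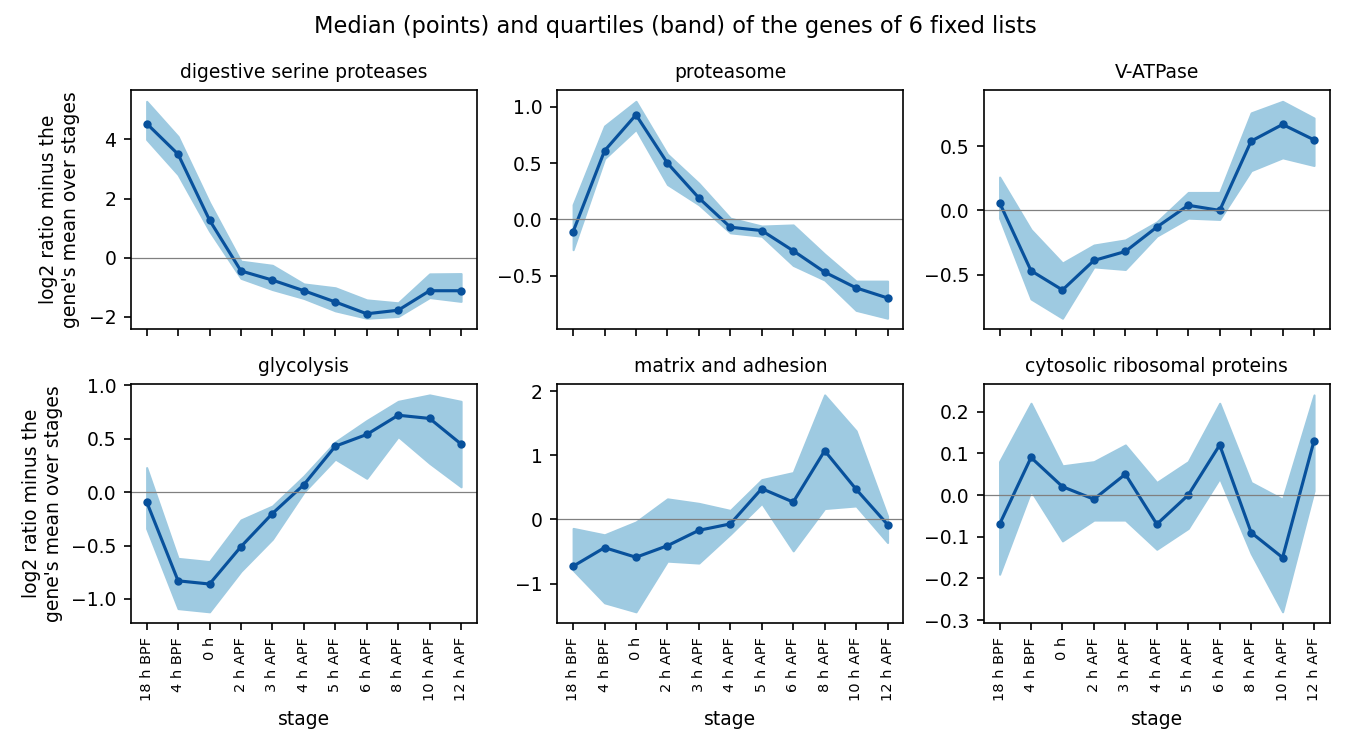
Median (points) and quartiles (band) over the genes of 6 fixed lists of the log2 ratio minus each gene's own mean over stages (y axis), by stage (x axis). Serine proteases go from 4.54 at 18 h BPF to -1.90 at 6 h APF, the proteasome is highest at 0 h (0.93), and ribosomal protein genes lie between -0.15 and 0.13.

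Between 6 h and 12 h APF, 8 of 16 DNA replication and cell cycle genes fell, and the largest rises were those of CG11570, CG7997 and Cht8. Cht8 went from -4.52 ± 0.88 to 3.19 ± 0.42 (SD, n = 3; change 7.71 ± 0.69, SE; adjusted p = 4.12e-09), and CG11570 and CG7997 rose by 8.28 ± 0.46 and 7.93 ± 0.60. The replication genes that fell included RnrL, the large subunit of ribonucleotide reductase (-2.13 ± 0.21), PCNA (-2.04 ± 0.28) and the replicative helicase subunit Mcm6 (-1.04 ± 0.24), and 1 gene of the list rose. Of 18 digestive carbohydrases, lipases and lysozymes 6 rose, such as Mal-A2 (2.94 ± 0.38) and LysP (2.25 ± 0.37), and none fell. Haemocyte markers fell in 4 of 7 cases, with Pxn, a matrix peroxidase, at -1.44 ± 0.31.

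The haemocyte calls also held NimC1 (-1.16 ± 0.34) and Col4a1 (-1.87 ± 0.58), each of which was lost without 6 h replicate c (-0.73 and -1.70) or 12 h replicate a (-1.04 and -1.65). Matrix genes were split: SPARC rose by a further 1.38 ± 0.31, while Timp changed by -1.09 ± 0.26 and 3 of 11 fell in all. The call of SPARC was lost under quantile normalization, at 0.86. V-ATPase genes rose in 6 of 21 cases, with Vha36-1 at 0.75 ± 0.20, and 1 fell. Proteasome genes fell in 8 of 29, Rpn5 to a change of -0.98 ± 0.24, and none rose. Serine proteases rose in 5 of 26 cases, thetaTry by 1.62 ± 0.50 and kappaTry by 2.22 ± 0.60. The call of kappaTry was lost without 6 h replicate c (1.16) and under quantile normalization (1.29). Glycolytic genes were split, with Gpdh1 at 2.11 ± 0.35 and Eno at -0.97 ± 0.20, 2 of 10 higher and 3 lower. Of 66 cytochrome P450 and glutathione transferase genes 19 rose, Cyp12a4 by 4.91 ± 0.40 and Cyp12a5 by 4.45 ± 0.46, and 10 fell, GstO3 to a change of -2.52 ± 0.27.

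Of 10 ecdysone regulators only Hr3 passed, with a change of -1.40 ± 0.40 (adjusted p = 0.016) that was lost without 6 h or 12 h replicate c (-1.29 and -0.61). EcR, br, Eip93F, ftz-f1 and Hr39 did not pass, at 0.73, 0.36, 0.53, 0.41 and 0.60. Among 13 cell death genes Damm rose by 1.05 ± 0.23 (adjusted p = 0.00106). Dark rose by 0.71 ± 0.22, lost without 6 h replicate b or 12 h replicate b or c (0.58, 0.73 and 0.69), and Dcp-1, an effector caspase, changed by -0.82 ± 0.24, lost without 6 h or 12 h replicate b (-0.68 and -0.74). Dronc and Diap2 did not pass, at 0.62 and -0.03.

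After CG11570, CG7997 and Cht8 the largest rises were those of CG14244 (6.47 ± 0.66, SE), SLC22A, a solute carrier gene (5.44 ± 0.46), and CG4362 (5.35 ± 0.45). The largest falls were those of CG1213 (-4.74 ± 0.38), CG11786 (-3.86 ± 0.55), Osi14 (-3.74 ± 0.63), CG14567 (-3.69 ± 0.30), Fer3 (-3.60 ± 0.45) and Mur89F, a mucin-related gene (-3.60 ± 0.34). In total 1981 of 9109 probes differed, 794 higher and 1187 lower at 12 h, in 1577 named genes. Among changes of at least 2-fold the balance turned, with 532 higher and 477 lower. Adjusted over the list alone, 9 replication and cell cycle genes fell, and 9 digestive carbohydrases, lipases and lysozymes and 7 V-ATPase genes rose. The camera test gave adjusted p-values of 0.0094 for replication, 0.0094 for the V-ATPase and 0.0196 for these digestive enzymes. All of them were lost when the correlation was estimated: replication and the digestive enzymes had adjusted p = 0.261 with an estimated correlation and the V-ATPase adjusted p = 0.461 with an estimated correlation. The digestive enzymes also lost their call under quantile normalization (adjusted p = 0.0969) and without 6 h replicate c (adjusted p = 0.0507), in a range from 0.000924 to 0.261 over the alternatives that use camera.

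Over the whole interval, from 18 h BPF to 12 h APF, the digestive serine proteases showed the most uniform fall among the fixed lists. Of 27 serine proteases 26 fell, Jon25Biii from 2.98 ± 0.47 to -4.41 ± 1.33 (SD, n = 3; change -7.38 ± 0.55, SE; adjusted p = 4.21e-11), and the median change was -5.75. Of 22 other digestive enzymes 14 fell, such as mag (-5.64 ± 0.62) and LysS (-3.23 ± 0.42), and 3 rose, tobi (3.76 ± 0.32), Mal-A2 (2.81 ± 0.38) and LysX (1.75 ± 0.21). Peritrophic matrix genes fell in 3 of 8 cases, Peritrophin-15a by the most (-5.70 ± 0.59). Chs2, a chitin synthase gene, rose by 5.32 ± 0.32, Cht8 by 6.36 ± 0.69, SPARC by 4.06 ± 0.31 and trol by 1.88 ± 0.29.

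Cell death genes rose in 2 of 12 cases, Buffy by 2.23 ± 0.26 (adjusted p = 1.4e-06) and Dronc by 1.77 ± 0.47 (adjusted p = 0.00648), the latter lost without 18 h BPF replicate b (1.40). Of 13 ecdysone regulators 2 rose, ftz-f1 by 0.70 ± 0.23 and Hr78 by 0.64 ± 0.18. The call of ftz-f1 was lost without any one of 18 h BPF replicates a, b and c and 12 h replicates a and b (0.73, 0.71, 0.66, 0.70 and 0.63), and that of Hr78 without 18 h BPF replicate a (0.56). Under quantile normalization both were lost, at 0.69 and 0.59. EcR, br, Eip93F, Hr3, Hr39, Blimp-1 and Diap2 did not pass, at 0.27, 0.12, 1.30, -0.63, 0.30, 0.32 and 0.08, and the probes of br disagreed in sign. Autophagy genes were split, 4 of 23 higher, such as Atg18a (1.23 ± 0.26), and 2 lower. Proteasome genes fell in 11 of 34 cases, Prosalpha7 to a change of -1.25 ± 0.22, and Prosalpha6 rose by 1.22 ± 0.22. Glycolytic genes rose in 5 of 11, among them Pfk (1.45 ± 0.21), V-ATPase genes in 7 of 22 with 2 lower, and matrix genes in 3 of 13. Oxidative phosphorylation genes rose in 7 of 56 cases. RpS5b was the only cytosolic ribosomal protein gene of 35 to pass (0.85 ± 0.24), a call lost without 18 h BPF replicate b (0.68) or 12 h replicate a (0.73).

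Apart from Cht8 and Chs2 the rises were largest for CG7997 (6.65 ± 0.60, SE), CG15169 (6.46 ± 0.44), CG11570 (6.13 ± 0.46) and CG16758 (5.93 ± 0.42). Ranked by single probes, the falls were largest for CG6839 (-7.71 ± 0.49), Jon25Biii, CG3819 (-7.37 ± 0.41), CG8664 (-7.33 ± 0.81), Jon65Aiii (-7.27 ± 0.96) and Jon65Aiv (-6.02 ± 0.45). On the gene means given here, thetaTry fell by more than Jon65Aiv. In total 2220 of 12704 probes differed, 1181 higher and 1039 lower at 12 h, in 1756 named genes. Adjusted over the list alone, 26 serine proteases, 16 other digestive enzymes and 13 proteasome genes fell, and 5 glycolytic, 3 matrix and 1 oxidative phosphorylation genes rose. Of the 13 lists that camera could test only the serine proteases passed (adjusted p = 5.61e-13), and they did so too when the correlation was estimated (adjusted p = 0.0453 with an estimated correlation). The other digestive enzymes, with 6 genes measured on every array, had an adjusted p of 0.594, while without the filter on missing values their 24 genes were lower as a list (adjusted p = 0.000981), in a range from 0.000981 to 0.782 over the alternatives that use camera.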

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

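All alternatives were planned except replicates b and c alone, which was chosen after seeing the data. Of 327 called values of named genes, 213 stayed past the threshold in every alternative run for single genes, 114 were lost in at least 1 of them (25 only when 1 array was left out), and 0 reversed. Single genes, whose values are already means over spots, were not rerun with only probes on all arrays or at a change of at least 2-fold. Except where a count shrank because fewer probes, fewer arrays or only changes of at least 2-fold were considered, the cause was not tested. Signal over background was not used here, so its limits are unknown.

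Under quantile normalization 3 probes passed from 3 to 4 h APF, 1 from 5 to 6 h, 148 from 6 to 8 h and 88 from 8 to 10 h. With array weights 634 passed from 4 h BPF to 0 h, 8 from 3 to 4 h and 3 from 4 to 5 h. Among the 2249 probes with values on all arrays, 1623 passed over the time course, 760, 855, 798 and 879 in the late larval, early prepupal, late prepupal and whole interval changes, 399, 174 and 346 in the steps up to 2 h, and 151, 86 and 155 in those from 6 h on. With only the 6 arrays compared 1207 passed in the late prepupal change, 11 from 3 to 4 h, 8 from 4 to 5 h, and 116, 52 and 150 in the last 3 steps. At least 2-fold changes numbered 1118, 1216, 1009 and 1368 in the 4 longer changes and 483 from 18 h to 4 h BPF. With replicates b and c alone 498 passed from 18 h to 4 h BPF, 377 from 0 to 2 h, and 108, 47 and 202 in the last 3 steps.

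Of the gene lists, 5, 6, 3 and 1 passed in the 4 longer changes. With an estimated correlation 1 late larval, 0 early prepupal and 0 late prepupal lists passed. The directional fry test passed 10 late larval and 7 whole interval lists, no filter 10 late larval, 7 late prepupal and 5 whole interval lists, and replicates b and c alone 8 late larval lists.

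Leaving out each array in turn gave 461 to 622 probes from 18 h to 4 h BPF, 158 to 328 to 0 h, 298 to 595 to 2 h, 0 to 1 from 3 to 4 h and from 4 to 5 h, 0 to 8 to 6 h, 105 to 404 to 8 h, 59 to 292 to 10 h and 194 to 285 to 12 h. Of the counts over all stages and for the longer changes none moved by over 1.5 times: 4000 to 4256 for the time course, and 1348 to 1638, 1460 to 2046, 1434 to 1980 and 1687 to 2068 for the longer changes. Arrays with the same letter tended to deviate together, a hint from the data and not from the labels: 29 of 33 arrays were closest to their own letter, and deviations from the stage mean correlated at a median of 0.107 over 165 pairs with the same letter (86 over 0.1) and -0.057 over other pairs. Not every pair exceeded 0.1, and the main model did not treat the arrays as paired. An effect shared by arrays of a letter is not excluded by this and stays in the error of that model. With the letter as a block 4443 probes passed over the time course, and no count moved by over 1.5 times.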

Other observations

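The tests of the matrix genes at 8 h and of the ratios at 10 h, and the comparisons of the short intervals with neighbouring steps lacking 1 array and of the noise with its spread between stages, were chosen only after the result was seen. Single members of further fixed lists passed the test. P450 and GST genes went both ways in the late larval change too, with 6 of 70 higher and 21 lower, Cyp6v1 at 1.75 ± 0.20 (SE) and Cyp6w1 at -4.33 ± 0.62. In the early prepupal change 15 of 60 rose and 16 fell, GstD1 by 1.96 ± 0.29 and Cyp12a4 at -4.75 ± 0.40. Lysosomal hydrolases were higher in 2 of 10 cases and lower in 2 in the late larval change, with Npc2a at 2.51 ± 0.28. The beta-galactosidase gene Gal rose by 4.10 ± 0.36 in the early prepupal change, when 2 of 11 rose and 4 fell, and over the whole interval the cathepsin gene CtsK1 rose by 3.39 ± 0.23, with 4 of 11 higher and 2 lower. Of 17 other ecdysone-induced genes 4 rose and none fell over the whole interval, Cth by 2.00 ± 0.17.

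Over the whole interval the immune amidase gene PGRP-SC2 changed by -4.80 ± 0.41 and PGRP-LF by 1.14 ± 0.25, the calls among 12 antimicrobial and peptidoglycan recognition genes. Of 4 small heat shock proteins Hsp27 rose by 1.93 ± 0.29 and l(2)efl changed by -3.95 ± 0.36. In the list of EGFR, Notch and other signals 3 of 16 rose, puc by 1.42 ± 0.29 and the EGF receptor ligand gene spi by 1.11 ± 0.22. Among markers of other cell types, 1 of 6 progenitor markers fell, Sox21a (-0.93 ± 0.23), although zfh2 rose by 1.76 ± 0.30 in the late larval change and changed by -1.68 ± 0.30 in the early prepupal one. Of 9 enteroendocrine markers 1 fell, CCHa2 (-1.45 ± 0.34), and of 4 fat body markers 1 fell, Lsd-1 (-0.92 ± 0.22). Of 5 Malpighian tubule markers 1 rose, ry (3.32 ± 0.34), and 1 fell. Of 6 salivary gland markers 1 rose, fkh (0.96 ± 0.34), a call lost without any one of the 18 h BPF replicates a, b and c (0.93, 0.89 and 1.07) and the 12 h replicates a, b and c (0.98, 1.05 and 0.86).

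No probe passed limma's test in the hourly steps from 2 h to 6 h APF, yet 1100 probes differed over the 4 h together. In the hourly steps 259, 329, 369 and 749 probes had unadjusted p-values under 0.05. For the first 3 steps that was less than chance alone would give at this threshold. Noisier arrays stay open for the window as a whole. The median SD between arrays averaged 0.226 from 2 h to 6 h and 0.246 at the other stages, a ratio of 0.92. The SE of that difference was 0.021. By stage the median SD was 0.237, 0.210, 0.189, 0.211 and 0.283 from 2 h to 6 h, and 0.304 at 10 h, in steps with calls. The values at 3, 4 and 5 h were below those of every other stage but 8 h (0.197). They argue against noisier arrays in the steps from 3 to 4 h and from 4 to 5 h. The test used a spread per probe estimated over all stages, not the spread of these stages alone. With only the 6 arrays compared, a few probes passed in each of these steps. Shorter intervals stay open too. The 2 h intervals inside the window had 82 and 59 calls, under a bound of 150. That bound rested on the 300 calls from 6 to 8 h, so it was drawn from these same data. The step from 8 to 10 h, equally long, had 173 calls. All of these counts moved with single arrays. The 82 calls from 2 to 4 h were 15, 2, 3 and 27 without 2 h replicates a and c and 4 h replicates a and b, the 59 from 4 to 6 h were 22, 14, 28, 99 and 32 without 4 h replicates b and c and 6 h replicates a, b and c, and the 300 were 120, 185, 147 and 105 without 6 h replicates a and c and 8 h replicates a and b. The spread of changes beyond error was 0 in the first 3 hourly steps, the lowest value it can take, and 0.225 from 5 to 6 h. It was 0.156 per hour from 2 h to 6 h together. Against this stood 0.108 per hour from 4 h BPF to 0 h, 0.262 from 0 to 2 h and 0.208 from 6 to 8 h. No biological explanation was tested for these steps.

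Of 10 testable matrix genes 5 were higher at 8 h APF than at 0 h, such as SPARC at 4.95 ± 0.31 (SE), Col4a1 at 4.66 ± 0.58 and trol at 2.99 ± 0.29, and 1 was lower, scb at -1.13 ± 0.26, with a median of 0.75 over all 13 genes. Fat body in the dissected gut stays open. The median over 5 fat body markers was -1.25, but none of those tested passed. apolpp, with 1 array at 0 h, was at 0.40. The comparison starts from a peak: relative to their own means over stages, 3 of the markers had a median of 1.22 at 0 h. It was -0.28 at 4 h BPF and -0.08 at 8 h. Fbp1 and Fbp2 are also in the list of other ecdysone-induced genes, so their fall need not mean less fat body. Haemocytes stay open: 7 markers outside the matrix list had a median of 0.11 but spread widely, with Hml higher at 8 h (adjusted p = 0.00554) and NimC1 at 4.00 and Pxn at 2.74, each with 1 array at 0 h. Haemocytes, fat body and expression by the gut itself could all contribute, and the arrays cannot separate them.

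At 10 h APF, the stage left out of the reference, 3 probes had stage means above 3.32, the limit that equal mixing of 10 stages sets, against 1 at 18 h BPF, which had a mean of 3.39, and 0 at each other stage. They were 2 probes of Treh (4.87 ± 1.27 and 3.65 ± 0.92, SD, n = 3) and 1 of CG5849 (3.39 ± 0.26). A single deviating array was argued against: in 2 of the 3 probes the middle 10 h array also lay above the limit, and each of the probes had another array as its highest. The absence of 10 h RNA from the reference may account for the 3 probes, although they are few and 1 pooled stage also passed the limit. No biological explanation was tested.

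The time course count of 4145 probes was reached by 1 of 100 splits of the arrays, the real one, and the highest other split gave 135. That is the smallest share these splits can give. The other splits put differences between stages into the error, which lowers their counts. They also ignore that arrays of a letter tended to deviate together. The count was thus above that of random splits, but chance is not excluded by this alone. For comparisons of 3 arrays with 3 the 10 possible splits are too few for a share under 0.05. In each of them with calls 1 split, the real one, reached the count. The real and highest other counts were 1777 and 131 for the late larval change, 1983 and 259 for the early prepupal, 1981 and 56 for the late prepupal and 2220 and 65 for the whole interval. For the steps they were 751 and 89, 315 and 14, and 608 and 2 up to 2 h APF, and 300 and 4 and 173 and 18 from 6 h to 10 h, and 132 higher with 180 lower against 44 from 10 to 12 h. In the 4 steps between, with 0 calls, all 10 splits reached the count, and the highest others were 0, 0, 1 and 9.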
